A study of Mus musculus with 4 samples.

How the data were processed

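RNA-seq was measured in 4 libraries of mouse regulatory T cells, labelled as biological replicates 1 to 4 of 1 group and as separate biosamples. The labels call the assay total RNA-seq but link a protocol for poly(A)+ libraries. They give the same donor identifier for all 4 and no sex or age. The labels do not say that each culture came from a separate animal. Sex-linked transcripts, described below, argue against a single animal for all 4, but do not tell how many animals were used. The p-values therefore measure only the spread between these libraries.

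The deposited files hold raw fragment counts per gene, made by the authors with featureCounts 1.4.6-p4 on mm10 with GENCODE M13, per the file headers. The headers show paired fragments with both ends mapped, reverse-stranded counting (setting 2) and exons grouped by gene. Names in the headers carry the word star2, and the aligner's version and settings are not given in the sources used here. The deposited files also give each gene's merged exon length. The design written before the data were examined assumed TPM and estimated counts, but the files hold only counts and lengths, so TPM was computed here from counts divided by length and scaled to the same total in each library. TPM of very short genes is unreliable, since fragments longer than the gene are counted on it. Genes overlapping ribosomal RNA sequence, such as Gm42418, which took 0.181% to 0.340% of counts, and near-identical copies are likewise uncertain.

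Of 50600 gene identifiers, 50376 matched a symbol when the version was ignored. Gene types came from GENCODE M21, and coordinates are those of the files. Total counts ranged from 51460018 to 121477975, a ratio of 2.36. A floor of 3 counts was used as the limit that a count of 0 allows. PCR copies were not marked by molecular identifiers in the sources used here, so counts cover counting error only.

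Levels are mean TPM ± SD over 4 libraries. Gene pairs were compared as the difference of log2(TPM + 0.1) within each library, with an exact two-sided sign-flip test and Benjamini-Hochberg adjustment over 20 pairs. Gene lists, written before the data were examined, were placed by the median of their mean log2(TPM + 0.1) among 10000 random lists of protein-coding genes of the same size. There were 25 lists of T cell and metabolic programmes, 9 of markers of other cells, 3 technical lists and 3 lists defined by symbol pattern. T cell receptor segments were summed by symbol prefix.

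Variability between libraries was tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr for 1 group, an intercept-only quasi-likelihood fit and a robust prior. The statistic was the quasi-likelihood dispersion over its trended prior, with adjusted p under 0.05 as the threshold, and the prior had 6.54 degrees of freedom. The filter needs enough counts in every library of the group, so it removes genes with few counts in some of them. Lists were tested by their median log2 dispersion ratio against 10000 random lists matched on expression deciles. In simulated counts for the 13625 tested genes, 0 genes were called without shifts, and 5.01% had an unadjusted p under 0.05. With 1 library shifted, 58.2% of genes with a 2-fold shift were called, and 100% of those with a 4-fold or 16-fold shift, with 9 unchanged genes called. Shifts were placed only on genes with higher counts. Dispersions were drawn for each gene separately from the prior fitted to these data, without genes moving together. These shares thus do not tell how many real shifts of that size would be called.

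Genes named for level are all genes of the pairs, the 3 highest members and the lowest member of each programme list, the 2 highest of each marker or technical list and the 10 most abundant nuclear protein-coding genes outside the ribosomal protein family. Genes named for variation are called genes of at least 5 TPM (at most 20), called list members (at most 4 per list) and the 5 called genes of largest range. Some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen. These are the Y-linked genes other than Eif2s3y, the 4 X-linked genes, Gm42418, and Sgk1, Lmna, Csf2, Penk, Cd24a, Gadd45b, Arhgap18 and Il27ra in the closing section, with the marker genes that its tests needed.

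Alternatives were a pseudocount of 1, CPM without length normalization, other detection thresholds, DESeq2 1.42.0 size factors and dispersion outliers, upper quartile normalization, no filter, a minimum of 50 counts, limma 3.58.1 with a trend, a prior without robust estimation, a threshold of 0.01 and leaving out each replicate. Removing each library's trend over GC content and length, thinning to equal depth and leaving out genes under 200 bp were added after seeing the data. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.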

Results

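The data were RNA-seq libraries from mouse regulatory T cells, the CD4 T cell subset that restrains immune responses and is defined by the transcription factor Foxp3. The labels gave 4 biological replicates of strain C57BL/6NJ in 1 group, and linked a protocol for differentiating CD4 T cells. Names in the file headers carried the words activated and 72 h. No second group was present, so levels of genes were compared within libraries, and spread was measured between them. Replicates 1 to 4 held 121477975, 62472060, 73690296 and 51460018 counts on genes. A count of 3, taken as the floor, was worth 0.0247 CPM in replicate 1, 0.0480 in replicate 2, 0.0407 in replicate 3 and 0.0583 in replicate 4. Intervals and floors of this kind cover counting error only.

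Of 50600 annotated genes, 23106 had a count in at least 1 library and 11984 reached 1 TPM in all 4 libraries. These 11984 included 10640 protein-coding genes and 428 long noncoding RNA genes. Among nuclear genes outside the ribosomal protein family, the elongation factor Eef1a1 was the most abundant, at 10577 ± 609 TPM (SD, n = 4). The cytoskeletal genes Actb (8879 ± 475 TPM), Tmsb4x (3147 ± 89.4 TPM) and Tubb5 (2175 ± 144 TPM) and the translation factors Eef2 (7780 ± 505 TPM) and Eif5a (2033 ± 79.9 TPM) followed, with the chaperone Hsp90ab1 at 5107 ± 188 TPM and the lactate dehydrogenase gene Ldha at 3279 ± 133 TPM. The cytokine gene Lta (2858 ± 167 TPM) and Il2ra, which encodes the alpha chain of the interleukin-2 receptor (2168 ± 242 TPM), completed the 10 most abundant genes. Replicates agreed closely: the median gene at 1 TPM in every library had a coefficient of variation of 8.53%, and 87.2% of these genes were under 20%. Pearson correlations of log2 TPM across these genes lay between 0.986 and 0.993 for the 6 pairs of libraries, where genes are not independent replicates. No pair agreed within sampling noise, as a library deposited again would, since the chi-square per degree of freedom was 16.9 or more over the 15836 to 17084 genes compared in each pair.

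The first comparison set Foxp3 against lineage-defining transcription factors of other CD4 T cells. Foxp3 (gene ENSMUSG00000039521.12, mm10 chromosome X, 7579676 to 7595243) stood at 448 ± 27.8 TPM (SD, n = 4). Gata3, the factor of Th2 cells (chromosome 2, 9857078 to 9890034), was at 49.4 ± 7.11 TPM, and Tbx21, the factor of Th1 cells (chromosome 11, 97098071 to 97115331), at 22.7 ± 5.23 TPM. Bcl6, which directs follicular helper T cells (chromosome 16, 23965052 to 23988852), was at 5.94 ± 1.09 TPM. Foxp3 exceeded Gata3 by 3.19 ± 0.19 on the log2 scale, Tbx21 by 4.33 ± 0.40 and Bcl6 by 6.23 ± 0.30, in 4 of 4 libraries each time. In the exact two-sided sign-flip test, 2 of the 16 sign assignments gave a difference as large for each pair, the fewest that 4 libraries allow, and the exact p was 0.132 after Benjamini-Hochberg adjustment over all 20 gene pairs. A comparison of transcript levels between genes depends on length normalization, and without it the difference from Tbx21 was 5.01 and that from Bcl6 5.49.

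**Figure D1:**
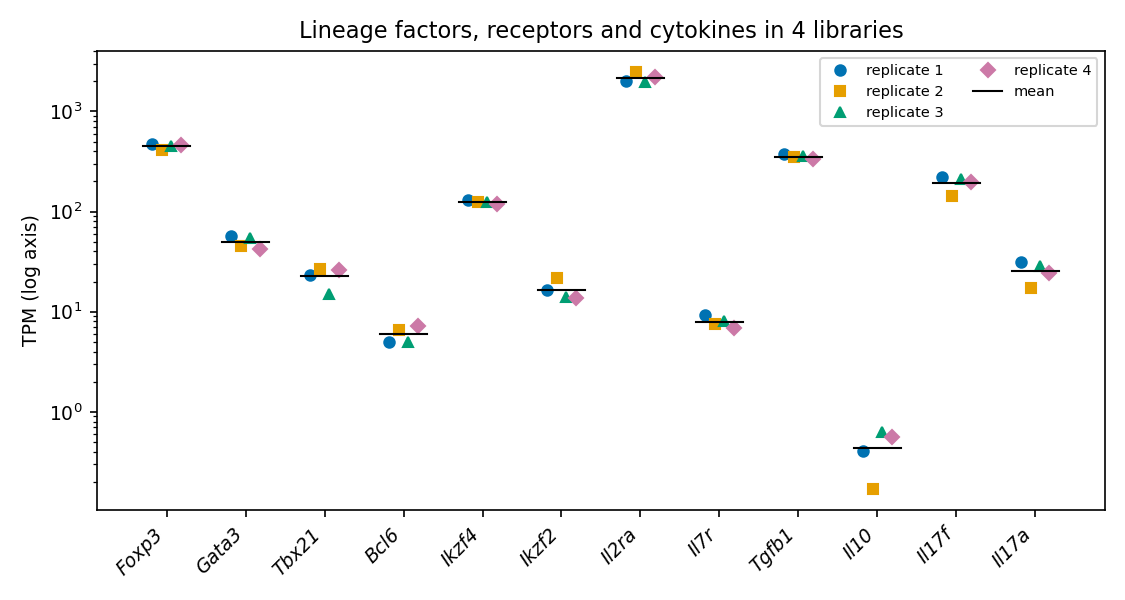
TPM on a log axis of 12 genes in each of the 4 libraries, with a horizontal line at the mean. Foxp3 lies at 448 TPM on average, above Gata3 at 49.4, Tbx21 at 22.7 and Bcl6 at 5.94, and Il10 is the lowest of the genes drawn at 0.439.

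The other 16 pairs set transcripts that mark alternative T cell states against each other. Cd4, the coreceptor of helper and regulatory T cells, was at 656 ± 16.2 TPM (SD, n = 4), against 0.243 ± 0.0456 TPM for Cd8a and 11.5 ± 2.16 TPM for Cd8b1. The alpha chain constant gene Trac was at 1182 ± 84.8 TPM and the delta chain constant gene Trdc at 1.16 ± 0.353 TPM. Among the Ikaros family factors, Ikzf4 (Eos) was at 124 ± 4.53 TPM and Ikzf2 (Helios) at 16.4 ± 3.61 TPM, so that Ikzf2 lay below Ikzf4 by a log2 difference of -2.93 ± 0.27. Ikzf1 was at 301 ± 16.8 TPM, and Foxp3 exceeded Ikzf2 by 4.78 ± 0.38. Il2ra exceeded Il7r, the interleukin-7 receptor gene carried by most other T cells, by 8.08 ± 0.30 (2168 against 7.93 TPM). Without length normalization the difference of Ikzf2 and Ikzf4 was -1.24, that of Foxp3 and Ikzf2 3.25 and that of Il2ra and Il7r 8.91.

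The inhibitory receptor gene Ctla4 (546 ± 94.8 TPM; SD, n = 4) exceeded the costimulatory receptor gene Cd28 (67.2 ± 9.05 TPM) by a log2 difference of 3.01 ± 0.07. Cd44, a marker of activated T cells, was at 191 ± 18.6 TPM. Tnfrsf18 (GITR, 824 ± 122 TPM) lay slightly below Tnfrsf4 (OX40, 1198 ± 98.3 TPM), by -0.55 ± 0.10. Nt5e (CD73), which makes adenosine from AMP, was at 135 ± 16.8 TPM, and Entpd1 (CD39), which acts before it in that pathway, at 4.05 ± 0.999 TPM. Gzmb (1.95 ± 1.06 TPM) exceeded Prf1 (0.350 ± 0.171 TPM) by 2.15 ± 1.02, and both cytotoxic granule genes were low. Without length normalization the difference of Ctla4 and Cd28 was 1.62 and that of Gzmb and Prf1 1.28, and the latter was 1.07 with a pseudocount of 1.

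Among the suppressive cytokines, Tgfb1 was at 354 ± 17.6 TPM (SD, n = 4) and Il10 at 0.439 ± 0.202 TPM. Il17a (25.5 ± 6.16 TPM) exceeded Il10 in 4 of 4 libraries. Il4 was at 0.0712 ± 0.0823 TPM, with 6, 0, 4 and 0 counts in replicates 1 to 4. Ifng was at 0.720 ± 0.588 TPM, and Il10 was above it in 2 of 4 libraries, with a log2 difference of -0.41 ± 1.52 (exact sign-flip p = 0.75). The remaining 15 pairs kept their direction in 4 of 4 libraries, each with 2 of 16 sign assignments as large and an adjusted exact p of 0.132.

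The fixed gene lists were then placed among random lists of protein-coding genes of the same size. Of the 16 genes of the regulatory T cell core, 15 reached 1 TPM in every library and 11 had a mean of 100 TPM or more, and the list median of 469 TPM lay at percentile 100 of the random lists. Il2ra, the actin-capping gene Capg (1242 ± 117 TPM; SD, n = 4) and Tnfrsf4 were its highest members. Itgae (CD103), an integrin that binds E-cadherin, was the lowest at 1.07 ± 0.193 TPM. The list of effector and tissue regulatory T cell genes lay at percentile 99.2. Its members Ccr8 (791 ± 35.7 TPM), Irf4 (786 ± 42.6 TPM) and Ccr4 (330 ± 38.1 TPM) were abundant, while Klrg1 had 0 counts in all 4 libraries. The suppressive effector molecules lay at percentile 67.3, with Lgals1 at 2016 ± 267 TPM, the inhibitory receptor gene Pdcd1 at 420 ± 41.2 TPM and Havcr2 at 0.305 ± 0.252 TPM. With only genes at 1 TPM in every library kept in the list and in the random lists, they were at percentile 97.1, and by the mean over all members at 99.3.

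Among the lists of helper T cell subsets, Th17 genes lay at percentile 92.3, with the chemokine receptor gene Ccr6 at 512 ± 21.2 TPM (SD, n = 4) and the cytokine gene Il17f at 193 ± 34.4 TPM, while Il22 had 0 counts. Th1 genes lay at percentile 80.0, with Il18r1 at 41.3 ± 7.41 TPM, Fasl at 25.3 ± 2.17 TPM and Stat4 at 25.1 ± 2.46 TPM. Follicular helper genes lay at percentile 71.5, with Cxcr5 at 28.6 ± 5.97 TPM, Sh2d1a at 20.4 ± 3.05 TPM and Il21 at 0.00945 ± 0.0189 TPM. Th2 genes lay at percentile 57.2, with the cytokine gene Il9 at 232 ± 37.6 TPM, Ecm1 at 39.0 ± 6.69 TPM and Ptgdr2 at 0 counts. With only genes at 1 TPM in every library kept, the percentiles were 31.0 for Th17, 6.41 for Th1, 25.0 for follicular helper and 43.4 for Th2 genes, and by the mean over members Th17 genes were at 96.3.

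T cell identity genes, with Cd2 at 926 ± 37.7 TPM (SD, n = 4), Thy1 at 926 ± 7.48 TPM and Cd27 at 35.4 ± 3.39 TPM, lay at percentile 100. So did T cell activation genes, with the antigen receptor-induced gene Nr4a1 at 965 ± 117 TPM, the transferrin receptor gene Tfrc at 703 ± 78.1 TPM and the growth factor gene Il2 at 8.09 ± 0.991 TPM. Targets of interleukin-2 and STAT5 also lay at percentile 100, with Lta and the feedback inhibitor gene Socs1 (409 ± 40.9 TPM) high and the survival gene Bcl2 lowest at 29.0 ± 2.57 TPM. The TGF-beta response list lay at percentile 99.5. Its repressor gene Ski stood at 185 ± 1.23 TPM, Tgfbr1 at 139 ± 13.2 TPM and Pmepa1 at 128 ± 8.43 TPM. Naive and quiescent T cell genes lay at percentile 99.8, with the lymph node homing receptor gene Ccr7 at 468 ± 64.0 TPM, Tcf7 at 449 ± 26.2 TPM, Igfbp4 at 135 ± 20.03 TPM and Il7r lowest. With only genes at 1 TPM in every library kept in the lists and in the random lists, the TGF-beta list was at percentile 92.2 and the naive list at 91.8.

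Cell cycle genes were high throughout. The list of G1/S and DNA replication genes lay at percentile 100, with the ribonucleotide reductase gene Rrm2 at 526 ± 10.01 TPM (SD, n = 4), the polymerase clamp gene Pcna at 501 ± 28.7 TPM, the helicase gene Mcm6 at 459 ± 14.5 TPM and E2f1 lowest at 50.2 ± 1.77 TPM. The mitotic list also lay at percentile 100, with Cdc20 at 450 ± 51.1 TPM, Top2a at 355 ± 21.7 TPM, Mki67 at 298 ± 24.8 TPM and Cenpf at 28.4 ± 1.78 TPM. All 14 members of each list reached 1 TPM in every library.

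Metabolic and stress lists also lay at percentile 100 each, with list medians of 411 TPM for glycolysis, 255 TPM for oxidative phosphorylation, 123 TPM for cholesterol synthesis, 159 TPM for the unfolded protein and integrated stress response and 197 TPM for apoptosis and p53. In glycolysis, Ldha was followed by Pkm (1857 ± 121 TPM; SD, n = 4) and Gapdh (1553 ± 114 TPM), and the glucose transporter gene Slc2a3 was lowest at 18.9 ± 2.40 TPM. Nuclear genes of oxidative phosphorylation included Cyc1 at 597 ± 34.2 TPM, Cox4i1 at 587 ± 40.8 TPM, Sdha at 336 ± 12.1 TPM and Ndufs1 at 51.6 ± 2.23 TPM. Cholesterol synthesis genes included the regulator Srebf2 at 560 ± 27.8 TPM, Hmgcs1 at 431 ± 33.7 TPM, Cyp51 at 416 ± 48.0 TPM and Idi1 at 38.2 ± 4.83 TPM. The unfolded protein and integrated stress response list included Atf4 at 637 ± 23.5 TPM, Hspa5 at 533 ± 7.04 TPM, Hsp90b1 at 527 ± 23.8 TPM and Dnajb9 at 10.2 ± 1.90 TPM. The apoptosis and p53 list included the cell cycle inhibitor gene Cdkn1a at 699 ± 45.2 TPM, Ccng1 at 397 ± 25.9 TPM, Bax at 365 ± 34.2 TPM and Bcl2l11 at 5.78 ± 0.144 TPM.

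The hypoxia list lay at percentile 99.6, with Egln3 at 258 ± 32.0 TPM (SD, n = 4), Hif1a at 132 ± 23.3 TPM, P4ha1 at 131 ± 9.91 TPM and Car9 at 1.94 ± 0.385 TPM. Immediate early and heat shock genes lay at percentile 98.4, with Junb at 1452 ± 132 TPM, Ier2 at 776 ± 95.4 TPM, Egr1 at 190 ± 3.82 TPM and Hspa1a at 0.759 ± 0.202 TPM. With only genes at 1 TPM in every library kept in the lists and in the random lists, the hypoxia list was at percentile 90.6 and the immediate early list at 83.5. Interferon response genes lay at percentile 41.5, with Irf1 at 12.5 ± 0.775 TPM, Isg15 at 3.36 ± 1.63 TPM and Rsad2 lowest at 0.00907 ± 0.0107 TPM. Only 4 of the 12 members reached 1 TPM in every library, and these lay at percentile 2.81 among random lists of such genes.

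Cytokine and chemokine genes lay at percentile 87.0 as a list of 33 members. Lta, Ltb (764 ± 62.1 TPM; SD, n = 4) and Tnfsf11, which encodes RANK ligand (416 ± 21.7 TPM), were its highest members. Chemokine receptor genes lay at percentile 80.1, with Ccr8, Ccr6 and Ccr7 highest and Ccr9 at 0 counts. When the lists and the random lists kept only genes at 1 TPM in every library, the cytokine list was at percentile 99.0 and the receptor list at 97.9. By the mean over all members the cytokine list was at 99.9. The list for retinoic acid response and gut homing lay at percentile 53.6. Its member Stra6, which encodes a retinol transporter, was at 327 ± 27.9 TPM, the integrin gene Itgb7 at 138 ± 9.38 TPM and the receptor gene Rara at 85.4 ± 5.41 TPM, while Rarb and the gut homing receptor gene Ccr9 had 0 counts.

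**Figure D2:**
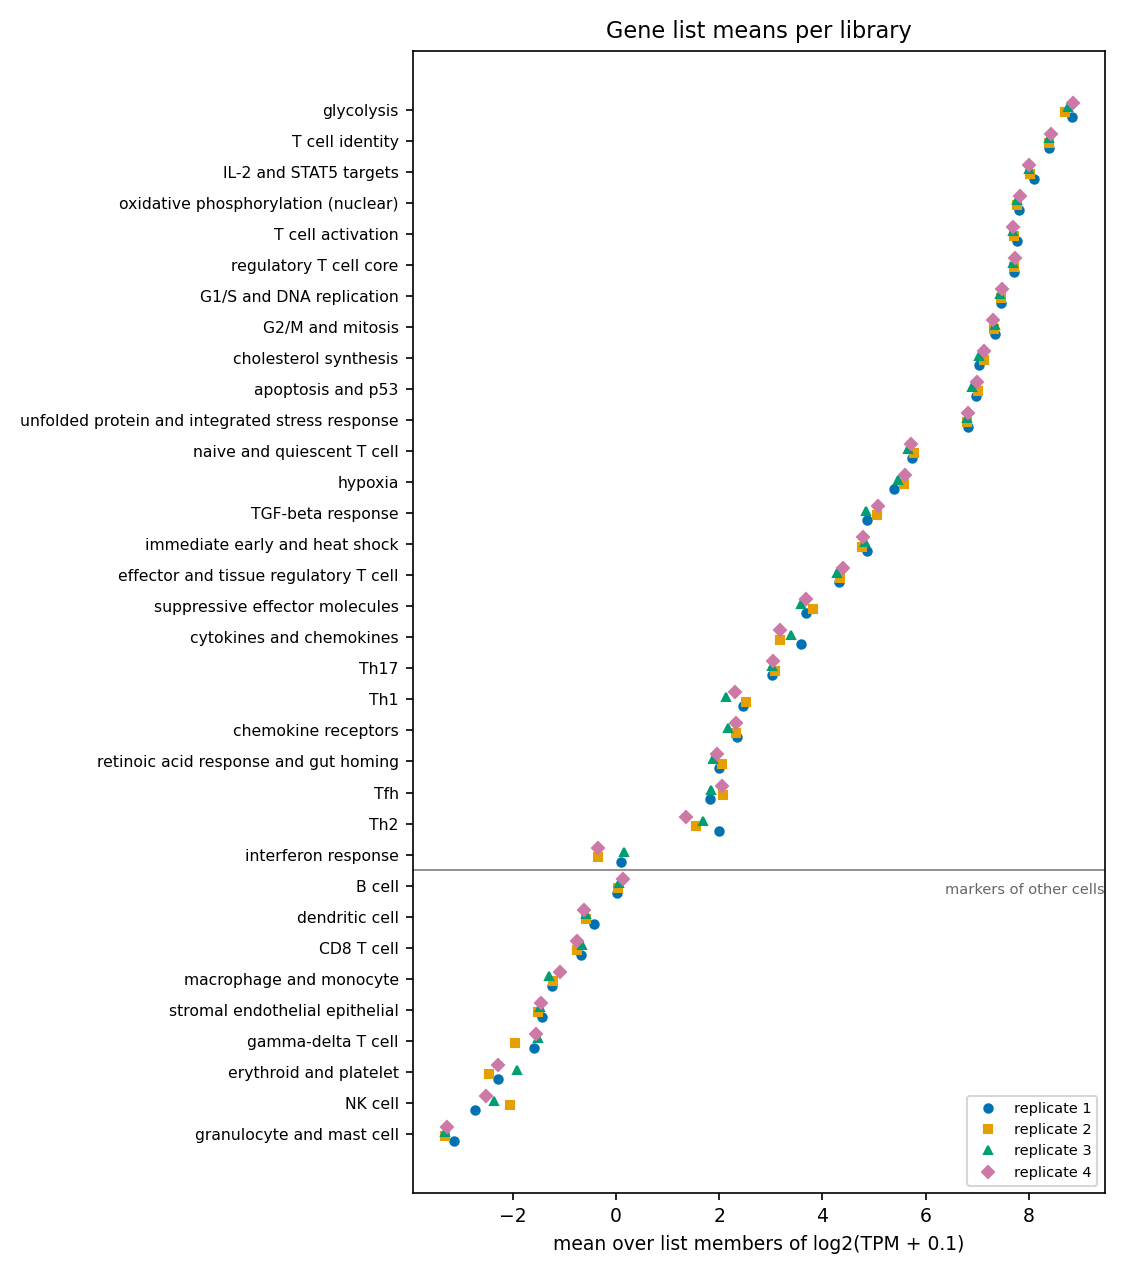
Mean over list members of log2(TPM + 0.1), per library, for the 25 T cell and metabolic lists above the grey line and the 9 lists of markers of other cells below it. Glycolysis lies highest at 8.79 and granulocyte and mast cell markers lowest at -3.27, averaged over the 4 libraries.

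Lists of markers of other cells lay at percentiles 14.1 to 42.4, below the middle of the random lists. B cell markers lay at percentile 42.4, with 11 members, and their 2 highest were the immunoglobulin genes Ighm (354 ± 22.3 TPM; SD, n = 4) and Igkc (17.0 ± 0.999 TPM). CD8 T cell markers lay at percentile 41.5, where Cd8b1 and Cd160 (1.61 ± 0.304 TPM) were highest, and gamma-delta T cell markers at 37.9, where Trdc and Tcrg-C2 (0.472 ± 0.285 TPM) were highest. Natural killer cell markers lay at percentile 21.5, with Fcer1g at 0.808 ± 0.711 TPM and Klrb1c at 0.148 ± 0.0312 TPM. Dendritic cell markers lay at percentile 18.4, although Cd74, the invariant chain of MHC class II, was at 600 ± 41.9 TPM and H2-Ab1 at 16.7 ± 2.63 TPM. Macrophage and monocyte markers lay at percentile 17.2, with Apoe at 10.3 ± 0.694 TPM and Cd68 at 4.51 ± 1.39 TPM.

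Erythroid and platelet markers lay at percentile 22.5, with Hbb-bt at 1.90 ± 0.690 TPM (SD, n = 4) and Itga2b at 1.01 ± 0.207 TPM. Stromal, endothelial and epithelial markers lay at percentile 15.2, with Pecam1 at 9.02 ± 0.756 TPM and Epcam at 3.12 ± 0.558 TPM. Granulocyte and mast cell markers lay at percentile 14.1, and their highest members, Cpa3 and Ms4a2, had 7 counts in replicate 1 and 1 count in replicate 4 respectively and 0 in the other libraries.

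Short noncoding RNAs that lack a poly(A) tail lay at percentile 28.9, with Rn7sk at 14.9 ± 1.16 TPM (SD, n = 4) and Rpph1 at 8.84 ± 4.59 TPM. The list labelled nuclear long noncoding RNAs lay at percentile 86.2, with Gas5 at 189 ± 13.2 TPM and Snhg1 at 97.7 ± 6.05 TPM highest. Where in the cell these transcripts lay was not measured. Replication-dependent histone genes, whose transcripts also lack a poly(A) tail, lay at percentile 41.8 and held 0.00249% to 0.00323% of the counts. The labels leave unclear whether poly(A) RNA was selected, so low levels of RNAs without a tail need not mean low expression in the cells. Cytosolic ribosomal protein genes lay at percentile 100 with 4.17% to 4.68% of the counts, and mitochondrially encoded genes at percentile 91.9 with 0.529% to 0.780%.

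The spread between replicates was examined gene by gene. Xist, the noncoding RNA that silences an X chromosome (chromosome X, 103460375 to 103483217), was the only one of 13625 tested genes that varied beyond genes of its abundance (edgeR quasi-likelihood dispersion test, adjusted p = 1.8e-05). Its level was 173, 199, 0.592 and 0.758 TPM in replicates 1 to 4. At an unadjusted p under 0.05 the test found 641 genes, 4.70% of those tested, against 5.01% in simulated counts without shifts. The prior was fitted to these same genes and the simulation drew from it, so this match does not show how much the libraries differ. DESeq2 marked 43 genes as dispersion outliers, limma-trend called 1, and edgeR called 98 without the filter on low counts and 18 without replicate 2. The filter removed the Y-linked genes of the sex-linked list, among which Eif2s3y had 0.0874, 0.133, 46.7 and 62.7 TPM in replicates 1 to 4. The sex-linked list as a whole lay at percentile 56.7, by means over all 4 libraries, which differ in these genes. Its member Xist passed the test over all genes and when adjusted over the list alone. The latter adds no support, since the Y-linked members were not tested.

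**Figure D3:**
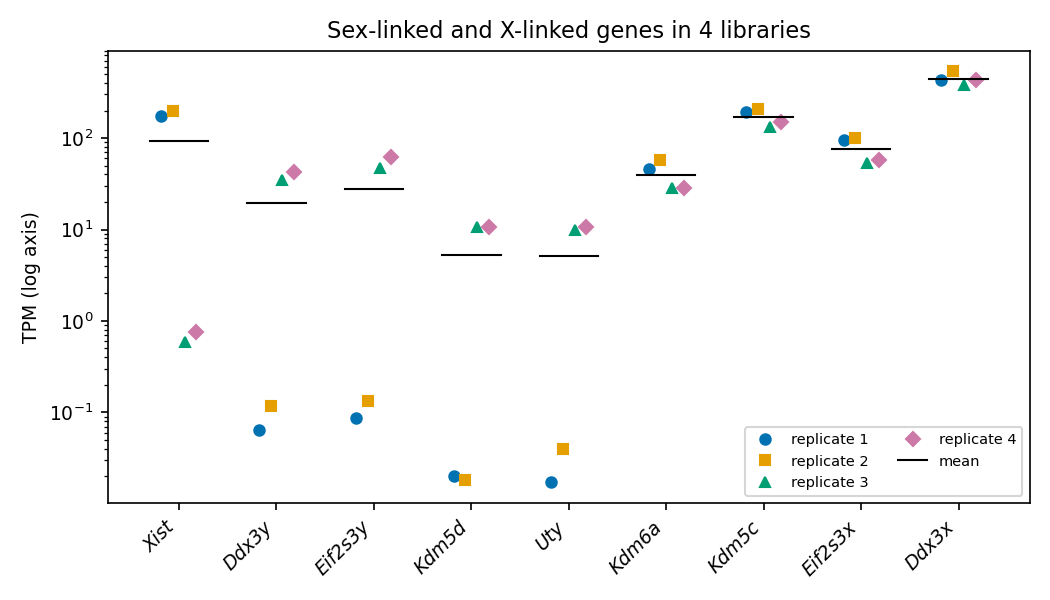
TPM on a log axis of Xist, 4 Y-linked genes and 4 X-linked genes in each of the 4 libraries, with a horizontal line at the mean. Xist is at 173 and 199 TPM in replicates 1 and 2 and at 0.592 and 0.758 TPM in replicates 3 and 4, and Eif2s3y shows the opposite split.

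Some fixed lists varied more between libraries than random lists matched on expression. Of 30 lists with at least 5 tested members, 7 did so after Benjamini-Hochberg adjustment. Mitochondrially encoded genes had a median log2 dispersion ratio of 2.83 and Th2 genes of 2.38, each with a permutation p of 0.0002 over 10000 random lists, the smallest they can give, and an adjusted p of 0.0030. Of the 13 mitochondrially encoded genes, 8 were tested and 2 had no count in any library, and the list median was 21.2 TPM. The cause of the missing counts was not tested, so this spread need not be one of expression in the cells. The other 5 were Th17 genes (1.81, adjusted p = 0.0040), follicular helper genes (1.93, adjusted p = 0.013), suppressive effector molecules (1.42, adjusted p = 0.013), cytokines and chemokines (0.82, adjusted p = 0.045) and the regulatory T cell core (1.05, adjusted p = 0.0497). Adjusted over the list alone, 7 mitochondrially encoded genes, 3 cytokine and chemokine genes and 1 gene of the retinoic acid and gut homing list passed the test of single genes, and 0 of them passed over all genes, while their counts at an unadjusted p under 0.05 were 7, 7 and 1.

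The cytokine gene Il17f, a member of both the Th17 and cytokine lists, had 221, 144, 213 and 195 TPM in replicates 1 to 4. The lists share genes and genes are not independent replicates, so these p-values describe only these libraries. The random lists drew genes separately, while genes of a list may move together, so the p-values can be too small. Without replicate 1, 3 lists passed, without replicate 3 also 3, and without replicate 4, 4 lists. Th2 and mitochondrially encoded genes passed in all 8 alternatives computed, Th17 genes in 7, follicular helper genes in 6, cytokines and chemokines in 5, suppressive effector molecules in 4 and the regulatory T cell core in 1. With a replicate left out, suppressive effector molecules passed in 0 of 4 settings, with a ratio of 0.40 without replicate 2, and cytokines and chemokines in 1 of 4.

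List means were close between libraries. The SD of the mean log2(TPM + 0.1) over the 4 libraries was 0.0113 for unfolded protein and integrated stress response genes, 0.0121 for mitotic genes, 0.0189 for G1/S and DNA replication genes and 0.0196 for the regulatory T cell core. It was larger for cytokines and chemokines (0.19), Th2 genes (0.27) and interferon response genes (0.28), and the median over the 25 lists was 0.0545. Interferon response means were 0.10, -0.35, 0.15 and -0.36 in replicates 1 to 4. Only 4 of the 12 interferon genes reached 1 TPM in every library, so genes with few counts weigh on these means. Matched on expression, the 6 tested members had a median log2 dispersion ratio of -0.0072 (adjusted permutation p = 0.99).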

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

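The tests of the variation between libraries over genes at an unadjusted p under 0.05, of antigen-presenting cells, of CD8 T cells and of pooled sexes were chosen after the result was seen, and the others were written before it.

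In 11 of 210 sets of 4 values tested, 1 library lay far from the other 3, measured as its gap to the nearest value over the whole range. Chance gives about 1 in 20, or 10.5 here. The gap ratio was 0.871 for the mean of T cell identity genes, where replicate 4 was highest, and 0.871 for the mean of chemokine receptor genes, where replicate 3 was lowest. It was 0.851 for the difference of Cd4 and Cd8b1 (replicate 1). Among single genes it was 0.896 for Itgae and 0.835 for E2f1 in replicate 4, 0.898 for Pdcd1 and 0.917 for Rara in replicate 2 and 0.880 for Egr1 in replicate 3. It was 1.000 for Il21, Cpa3 and Ms4a2, which had counts in only 1 library, of 3, 7 and 1.

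Xist was at 173, 199, 0.592 and 0.758 TPM in replicates 1 to 4, while the summed TPM of Ddx3y, Eif2s3y, Kdm5d and Uty was 0.189, 0.308, 102 and 127. If the animals differed in sex, X-linked genes that escape silencing would be higher in both libraries with Xist, and 3 of the 4 examined (Kdm6a, Kdm5c and Eif2s3x, but not Ddx3x) were. Pooling of both sexes within a library was argued against, since in each library either Xist or the Y-linked genes stayed at or under 0.380% of their highest level. The opposite levels of Xist and the Y-linked genes argue against a single animal as the source of all 4 libraries. Animals of different sex may therefore be a source of this split. The labels give no sex to set it against, and the donor identifier they give is the same for all 4 libraries.

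The 641 genes at an unadjusted p under 0.05 were 4.70% of those tested, against 5.01% in simulated counts without shifts. The simulation drew from a prior fitted to these genes, so this match does not show how much the libraries differ. Of the 641 genes, 543 (84.7%) had replicates 1 and 3 on one side and replicates 2 and 4 on the other. This compares with 51.5% of all 13625 tested genes and 33.3% for unrelated genes, although genes move together and any shared factor gives such a share. Removing the trend over GC content and length left 79.6%, and the split that Xist follows held 9.67%, which argues against each as the whole cause. The tests written beforehand ran over called genes, and with 1 called gene they decide nothing: 100% of the called genes stayed called without the GC and length trend, replicate 1 was farthest in 0% and the Xist split held 100%. Replicates 1 and 3 were also the deepest libraries (121477975 and 73690296 counts, against 62472060 and 51460018), and thinning to equal depth, which left 84.1%, keeps the expected ratios of genes, so that depth cannot be told apart from the split. Shared culture days or library batches, not given in the sources used here, stay open too, and no biological explanation other than sex was tested.

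Ighm (354 TPM), Cd74 (600 TPM) and Cd8b1 (11.5 TPM) are markers of other cell types. B cells would bring immunoglobulin V segments, but these held at most 0.175% of the counts of Ighm, Ighd and Igkc. CD8 T cells would bring Cd8a, which was at most 3.67% of Cd8b1. For antigen-presenting cells, Lyz2, H2-Aa, Itgax, Csf1r and Adgre1 had a summed TPM of at most 0.630% of that of Cd74. All 19 other members of the macrophage and dendritic lists had at most 7.37%, mostly from H2-Ab1 and Apoe. The latter share lay between the limits set for and against such cells, so by itself it decides nothing. The median member of either list was at most 0.00997% of Cd74, and 6 members, Lyz2, C1qa, C1qb, Cd209a, Clec9a and Siglech, had 0 counts. The tables thus argue against B cells as the main source of Ighm, CD8 T cells as that of Cd8b1 and antigen-presenting cells as that of Cd74, a smaller share of such cells stays open, and transcription of these genes in the T cells is a candidate explanation that was not tested.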

How the results depend on the processing

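The GC and length correction, thinning and the omission of short genes were chosen after seeing the data. The number of genes detected, the number of lists at or above percentile 95 (15 to 19, against 16) and the 15 pairs with 1 direction stayed within 1.5 times their value in every alternative computed. Without length normalization Foxp3 exceeded Tbx21 by 5.01 and Bcl6 by 5.49 on the log2 scale, because the genes differ in length. The number of genes varying between replicates was 98 without the filter on low counts, 43 as DESeq2 dispersion outliers and 1 to 18 with a replicate left out; 18 came without replicate 2 and 2 without replicate 1. Xist was called in each. Of the 98, 91 pass the filter and were tested with it too, and the prior degrees of freedom were 32.9 without it against 6.54; the cause was not tested. The number of more variable lists was 3 to 8 with a replicate left out, and the cause was not tested. The difference of Il10 and Ifng, both under 1 TPM on average, ran from -0.92 to 0.040 with a replicate left out and turned sign without replicate 1 (0.0099) and without replicate 2, and the cause was not tested. With a replicate left out, the mean TPM moved by over 1.5 times for genes such as Ifng (0.720 to 0.456 without replicate 1), Havcr2 (0.305 to 0.183) and Fcer1g (0.808 to 0.486, both without replicate 2). Of 225 list percentiles recomputed, 11 crossed 95, and of 32 values of the other pairs under another pseudocount or without length normalization 19 moved by more than 1 SD. Alternative TPM from an expression estimator was not run, since it was not part of the data used here. Depth limits genes such as Il4 and Il21, with 6 counts or fewer in any library.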

Other observations

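T cell receptor counts fell on many beta chain V segments. Trbv31 held 11.0 ± 1.39% of Trbv counts (SD, n = 4), Trbv19 11.0 ± 0.637%, Trbv13-2 9.54 ± 0.587%, Trbv3 9.51 ± 0.479% and Trbv1 9.22 ± 0.957%, and 18 of 22 segments annotated as V genes were above 1% in every library. The libraries held 6537 to 13551 such counts. Delta chain segments (Trdv) held 119 counts in all 4 libraries together.

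Other genes with an unadjusted p under 0.05 in the edgeR test, chosen after their values were seen, included the neuropeptide precursor gene Penk, at 215, 128, 142 and 112 TPM in replicates 1 to 4. Cd24a was at 6.44, 31.1, 8.11 and 20.99 TPM, and Gadd45b at 87.9, 43.8, 92.5 and 51.7 TPM. Arhgap18 was at 10.5, 11.0, 2.02 and 9.44 TPM, and Il27ra, which encodes the interleukin-27 receptor, at 56.7, 47.4, 29.6 and 24.3 TPM. Values were 56.7, 111, 49.8 and 88.5 TPM for Sgk1, 32.3, 15.3, 32.8 and 18.3 TPM for Lmna and 27.5, 7.06, 24.8 and 12.9 TPM for Csf2. With the filter on low counts and all 4 libraries, 0 of these 8 genes passed the adjusted threshold in edgeR. All 8 were among the 98 genes called without the filter and the 43 dispersion outliers of DESeq2, and all but Gadd45b and Csf2 among the 18 called without replicate 2.

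Library deviations from the mean followed GC content across 11631 genes, with Spearman correlations across genes of 0.41, -0.54, 0.26 and 0.18 for replicates 1 to 4. GC content and gene length together accounted for 8.09%, 18.3%, 2.84% and 1.35% of the variance of these deviations.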
